A study of Mus musculus with 2 samples.

How the data were processed

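H3K9ac chromatin immunoprecipitation and sequencing was carried out, per the labels, on forebrain of B6NCrl mouse embryos at embryonic day 16.5, with 2 biological replicates from separate biosamples of pooled male and female embryos and a library size range of 300 to 500 bp. The labels give 1 group. Per the labels and the text deposited with the files, peaks are on mm10. The list of replicate 1 was made from its filtered alignments and 2 external files, that of replicate 2 from its alignments and 1 of these, the pooled list from the alignments of both replicates and both external files, and the replicated list from the pooled list and both replicate lists. What the external files hold, the aligner, the peak caller and its version, and the rule that made a peak a replicated one are not given in the sources used here. All 34941 replicated peaks were found in the pooled list.

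Each deposited peak carries a fold, the authors' ratio of enrichment over background at the peak. The lists also hold the authors' −log10 p-value and −log10 q-value of each peak, and the deposited distance in bp from the peak's start to its summit. The lowest −log10 p-value was between 2.00 and 2.05 in the 4 deposited lists, and 8.12% of peaks of replicate 1, 8.10% of replicate 2, 5.76% of the pooled and 1.63% of the replicated list had a q-value above 0.05. No read counts or depths are given, so no interval of a fold could be had, and folds were not compared as levels between lists. The different external files behind each list and the unknown depths could change the number of weak peaks a list holds.

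Coordinates were checked against chromosome lengths of GRCm38.p6 and annotated with GENCODE mouse release M21. Positions are 1-based. Promoters were taken as within 1000 bp of a start of any protein-coding transcript, so a peak between neighbouring starts counts for both genes. Peaks elsewhere were assigned to gene bodies or to sequence between genes. Distal peaks lay over 2500 bp from any protein-coding start and were assigned to the gene with the nearest start. CpG-rich promoters had an observed/expected CpG of at least 0.6 and a GC fraction of at least 0.5 within 500 bp of the start. A gene counted as CpG-rich if any of its starts was, and as marked if any of its starts had a peak. Domains were replicated peaks merged over gaps of at most 1000 bp. Protein-coding genes on chromosomes 1 to 19 and X were counted, 21670 in all. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9.

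Replicates were compared by overlap of at least 1 bp against 1000 random placements that kept peak lengths and chromosomes, by rank correlation of folds over overlapping pairs, and by Cohen's kappa over genes. The share of peaks at promoters was set against 1000 random placements in the same way. Both placement tests were one-sided. Each gene list was compared with all other protein-coding genes by a two-sided Fisher's exact test, and its mean number of distal peaks with 10000 random lists of the same size by a two-sided permutation test, each with Benjamini-Hochberg adjustment over 27 lists and a threshold of 0.05. Genes with and without a CpG-rich promoter, and X-linked and autosomal genes, were compared by two-sided Fisher's exact tests. The position of summits within 1000 bp of a start was described with an exact binomial interval of 95%.

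The 27 lists, the tests and the rule for named genes were fixed before the data were examined. The lists were housekeeping, radial glia, intermediate progenitor, pan-neuronal, deep-layer projection, upper-layer projection, GABAergic and ganglionic eminence, Cajal-Retzius, diencephalon, oligodendrocyte lineage, astrocyte, microglia, endothelial and pericyte, erythroid, choroid plexus, meninges and fibroblast, midbrain and hindbrain, Hox, liver, heart and muscle, germline and pluripotency, immediate early, cell cycle, chromatin acetylation, axon guidance, adult synapse, and imprinted genes. The genes Btg2, Cspg4, Egr2, Igf2, Lhx2 and Snap25 are in 2 lists each. Ahsp, H19, Meg3 and Kcnq1ot1 were not among the protein-coding genes counted and were left out. Named were, in each list, up to 4 genes with the largest promoter fold and up to 3 without a peak in alphabetical order (all where at most 5), the genes of the 15 widest domains, the 10 promoter peaks and 10 distal peaks of largest fold, and the 5 strongest peaks of each replicate that the other lacked.

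Alternatives were an overlap of 50% of both peaks, only peaks of −log10 q of at least 5, equally many top peaks in both replicates, each replicate's own list in place of the replicated list, the pooled list, promoter windows of 500 and 2500 bp, only the gene's own 5′ end, random lists matched on promoter CpG and GC deciles, a background without olfactory, vomeronasal and predicted genes, a distal distance of 5000 bp, random lists matched on deciles of the length of sequence nearest to the gene, a CpG threshold of 0.75 with GC of 0.55, and a summit window of 500 bp. Placement tests under alternatives used 100 placements. Lists matched on CpG and GC content were drawn from all other protein-coding genes, olfactory and vomeronasal receptor genes included. Restricting the replicated list to peaks overlapping both replicates was added after the data were seen.

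The tests were tested on simulated data, over the same 21670 genes for lists and promoters and over 20000 peaks for overlaps. Of 180 planted gene lists with a peak at 10% of members against 60% elsewhere 164 were called lower (91.1%), and of 360 unchanged lists 3 were called (0.833%). Of 9 lists planted with a mean of 2 distal peaks against 0.5 elsewhere all 9 were called, and 1 of 18 unchanged lists was called (5.56%). These counts were drawn from Poisson distributions. The real counts were more uneven, with a 90th percentile of 2 per gene and 77 nearest to Gse1, so both rates need not hold for the data. All genes given one of 12858 planted promoter peaks and all 12000 planted overlaps were found. The peaks were planted inside the promoter window and the overlaps as shifted copies, so this checks the counting and not detection in real data. Peaks on the Y chromosome and on unplaced sequences were left out of gene counts.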

Results

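Acetylation of lysine 9 of histone H3 (H3K9ac), a chromatin mark found at active gene starts, was profiled by chromatin immunoprecipitation and sequencing in mouse forebrain at embryonic day 16.5. There was 1 group with 2 biological replicates, each a separate pool of male and female B6NCrl embryos, and the pool of replicate 2 held 41 embryos. Each replicate had its own peak list, and the series added a list called on both replicates pooled and a list of replicated peaks. The peak lists hold no read counts, so the sequencing depth of each library is unknown. Replicate 1 had 51867 peaks covering 32.0 Mb, and replicate 2 had 41534 peaks covering 27.6 Mb. The pooled list held 43776 peaks, and the replicated list, on which most of what follows rests, held 34941 peaks covering 29.7 Mb or 1.09% of the mm10 chromosomes. With 1 group there was no comparison between conditions, and the questions left by the design were how far the replicates agreed and which genes and regions carried the mark. Genes and peaks are not replicates, so every test below describes these libraries. The fold given for a peak is the authors' own enrichment over background, used to describe and rank peaks within 1 list and, across the replicates' lists, only in correlations over overlapping peak pairs. Intervals are exact Clopper-Pearson 95% intervals that cover counting error only.

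Strong promoter peaks were found in both replicates, and most peaks seen in 1 replicate were weak and narrow. Of the promoter peaks, 88.4% of those in replicate 1 and 94.2% of those in replicate 2 overlapped a peak of the other replicate by at least 1 bp. In gene bodies the shares were 38.2% and 60.6%, and between genes 47.7% and 68.4%. The strongest peak of replicate 1 with no partner lay in an intron of Mcoln2, a lysosomal cation channel gene, at chromosome 3, 146177782 to 146178401, with a fold of 8.24. The next lay nearest to Gm5617 (8.004) and Atp10a (7.95), in an exon of H6pd (7.55) and at the start of Susd6 (7.55). In replicate 2 the strongest lay 3953 bp from the start of Ascl1, a proneural transcription factor gene, at chromosome 10, 87489381 to 87489864, with a fold of 7.87. It was followed by peaks at the starts of the histone gene Hist1h2ae (7.21), the chloride transporter gene Clcn5 (7.21) and Atp6v1b2 (7.21), and by a peak nearest to Slc15a5 (7.17). Histone genes are near-identical copies, so the placement of the Hist1h2ae peak is uncertain.

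Across all peaks, 31525 of 51867 in replicate 1 (60.8%, interval 60.4 to 61.2%) and 32655 of 41534 in replicate 2 (78.6%, 78.2 to 79.0%) overlapped the other list. Random placement gave 2.22% ± 0.0728 (SD, 1000 placements) and 2.75% ± 0.0920, and the one-sided permutation p was 0.000999 in both directions, the smallest that 1000 placements can give. The 20342 peaks of replicate 1 without a partner had a median fold of 3.24 and a median width of 213 bp, beside 6.91 and 648 bp for those with one. The 8879 such peaks of replicate 2 had a median fold of 3.49 and a median width of 209 bp, beside 6.87 and 578 bp. Promoters held 11.9% and 13.2% of the peaks without a partner. In the highest fold decile, 100% of peaks overlapped in each replicate, against 23.96% and 52.4% in the lowest. The lowest overlap was in the next decile up, with 22.02% in replicate 1 and 45.2% in replicate 2. Across 28924 peak pairs the folds had a Spearman rho of 0.90 and a Pearson r of 0.915 on the log2 scale, given without a p because peaks are not independent. Rho was 0.903 over 17063 promoter pairs and 0.646 over 11861 other pairs. The number of peaks without a partner depended on the threshold: with only peaks of −log10 q of at least 5 it was 4379 in replicate 1 and 1226 in replicate 2. Requiring an overlap of 50% of both peaks raised it to 17079 in replicate 2, and taking equally many top peaks from each list gave 12117 in replicate 1 and 10461 in replicate 2.

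**Figure D1:**
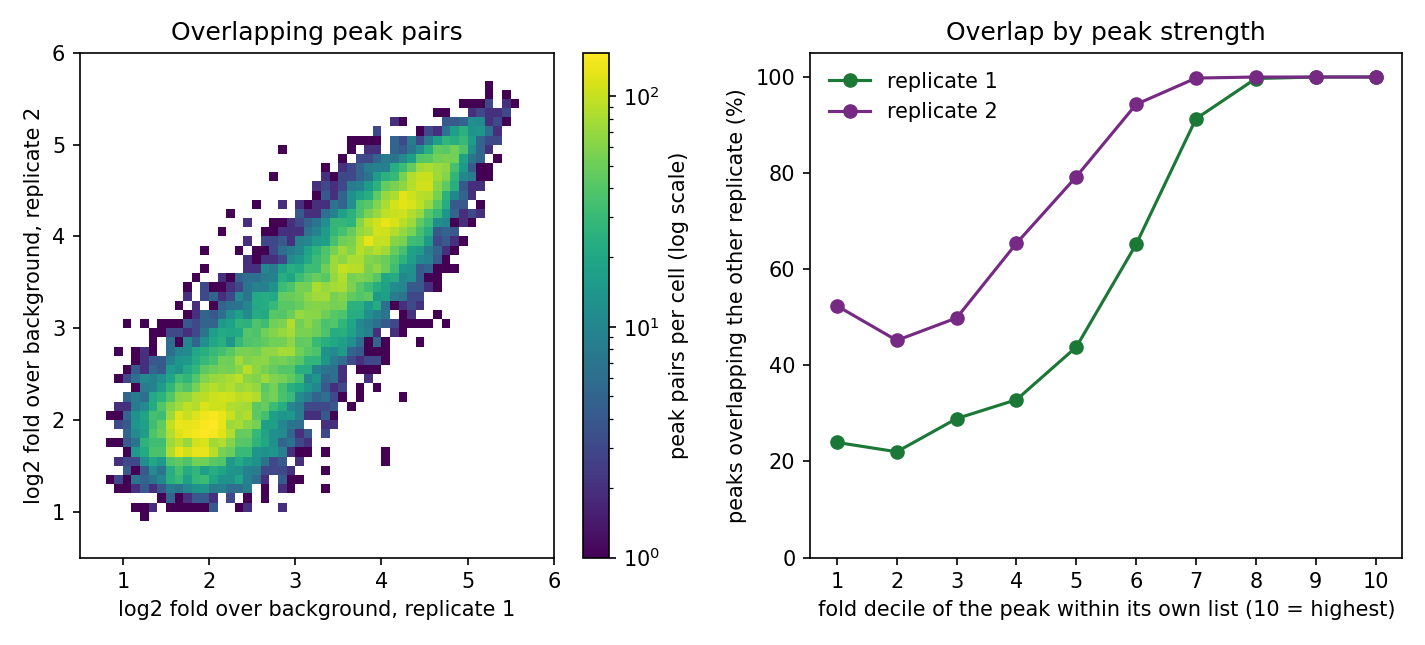
The left panel shows log2 fold over background in replicate 1 against replicate 2 for 28924 overlapping peak pairs, with colour giving pairs per cell on a log scale (Spearman rho 0.90). The right panel shows the percentage of peaks overlapping the other replicate by fold decile within each list, which is lowest in decile 2 (22.02% in replicate 1 and 45.2% in replicate 2) and 100% in decile 10 of both.

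The strongest peaks lay at gene starts. The promoter peak of largest fold was at Srsf6, a splicing factor gene (53.2, chromosome 2, 162930572 to 162932518). It was followed by the histone methyltransferase gene Kmt5b (52.7, chromosome 19, 3767008 to 3769325) and the cytoskeletal actin gene Actb (51.9, chromosome 5, 142904608 to 142906745). Next came the nuclear import gene Tnpo1 (51.5), the deubiquitinase gene Usp22 (51.1), the acyltransferase gene Mboat2 (50.5), the RNA-binding protein gene Mex3b (49.3), the transcription factor gene Klf7 (49.1), Basp1, which encodes a growth cone protein (48.5), and the transcription factor gene Sp3 (48.5). Promoters, taken as within 1000 bp of a protein-coding transcript start, held 18469 replicated peaks, or 52.9% (interval 52.3 to 53.4%). Random placement gave 3.68% ± 0.103 (SD, 1000 placements), a ratio of 14.4, with a one-sided permutation p of 0.000999, the smallest possible. Of the strongest 1000 replicated peaks, 973 were at promoters, as were 96 of the strongest 100.

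Promoter peaks were also the widest class. Their median fold was 13.3 (quartiles 6.67 to 20.9) and their median width 995 bp, and they held 71.6% of the covered sequence. Gene bodies held 9004 peaks (25.8%) with a median fold of 3.96 and a median width of 358 bp. Between genes there were 7459 peaks (21.4%) with a median fold of 4.38 and a median width of 402 bp. In the replicates' own lists the promoter share was 40.3% in replicate 1 and 48.6% in replicate 2.

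Of 21670 protein-coding genes on the autosomes and X, 13843 carried a replicated promoter peak (63.9%, interval 63.2 to 64.5%), with a median fold of 17.6 (quartiles 11.4 to 23.6). The replicates' own lists gave 14032 genes (64.8%) and 13828 genes (63.8%). Both lists marked 13647 genes, only replicate 1 marked 385, only replicate 2 marked 181 and neither marked 7457, a Cohen's kappa of 0.943.

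Genes with a CpG-rich promoter nearly all carried the mark, and X-linked genes carried it less often than autosomal genes. A promoter peak was present at 97.4% of genes with a CpG-rich promoter (10655 with and 284 without) and at 29.7% of the other genes (3188 with and 7543 without), a difference of 67.7 points that was past the threshold of a two-sided Fisher's exact test. In a gene with several starts the peak need not lie at the CpG-rich one. Of X-linked genes 48.2% had a promoter peak (457 with, 491 without), and of autosomal genes 64.6% (13386 with, 7336 without). The difference of −16.4 points had a two-sided Fisher's exact p of 9.72e-24. Against autosomal genes matched on promoter CpG and GC content the X difference shrank to −2.88 points, with a two-sided permutation p of 0.0064 over 10000 draws. The matched genes included the seldom marked olfactory and vomeronasal receptor genes, which can make this difference smaller. Without these and predicted genes the unmatched difference was −16.7 points, and matching without them was not run.

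The 27 gene lists fell into those marked at nearly every member, those marked at few and those not past the threshold of the test, beside 63.9% of other genes. All 15 housekeeping genes carried a promoter peak, among them Actb (fold 51.9), the ribosomal protein gene Rpl13a (37.3), the signalling adaptor gene Ywhaz (31.3) and the elongation factor gene Eef1a1 (31.3). All 14 genes of chromatin and histone acetylation were marked, with the acetyltransferase gene Ep300 (41.8), the deacetylase gene Hdac2 (32.7), the remodeller gene Smarca4 (31.7) and the acetyl-lysine reader gene Brd4 (30.4) highest. All 12 cell cycle genes were marked, including Ccna2 (19.6), Mcm5 (18.4), Mki67 (13.7) and Mcm2 (13.1). All 12 immediate early genes, whose transcription responds fast to stimulation, were marked as well, with Dusp1 (27.4), Btg2 (19.8), Nr4a1 (18.7) and Jun (17.6) highest.

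Lists of radial glia, neurons, axon guidance and the synapse were marked at every member but 1. All 15 radial glia genes had a peak, among them the telencephalic transcription factor gene Foxg1 (30.1, peak at chromosome 12, 49375441 to 49383812), the cortical selector gene Lhx2 (25.5), the stem cell surface gene Prom1 (25.2) and the progenitor transcription factor gene Sox2 (17.5). All 15 pan-neuronal genes had one, with the adhesion gene Ncam1 (37.3), the microtubule genes Map2 (35.1) and Tubb3 (29.99) and the splicing factor gene Rbfox3 (29.0) highest. The 10 deep-layer projection neuron genes were all marked, including Bcl11b (36.7), Tle4 (23.5), Tbr1 (21.9) and Foxp2 (21.6), which encode transcriptional regulators. So were the 11 upper-layer genes, including Pou3f2 (31.9), Pou3f3 (31.5), Cux1 (27.1) and Satb2 (25.8). Of 18 GABAergic and ganglionic eminence genes 17 were marked, with Meis2 (31.0), Dlx5 (22.6), Ascl1 (19.7) and Dlx1 (15.1) highest and the neuropeptide gene Sst without a replicated peak. All 15 axon guidance genes were marked, including the receptor gene Plxna4 (23.4), the ligand genes Sema3a (20.9) and Efna5 (20.1) and the receptor gene Ephb2 (20.1). The 16 genes of the adult synapse were marked too, with the glutamate receptor gene Gria2 (26.1), the scaffold genes Homer1 (26.0) and Dlg4 (23.2) and the GABA receptor gene Gabra1 (22.4) highest.

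These 11 lists lay above other genes. The adjusted p of the two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 27 lists, was 0.00504 for the housekeeping, radial glia, pan-neuronal, axon guidance and synaptic lists. It was 0.00827 for chromatin acetylation, 0.0111 for the GABAergic, immediate early and cell cycle lists, 0.0177 for upper-layer genes and 0.0292 for deep-layer genes, each by the same exact test. Against random lists matched on promoter CpG and GC content only the pan-neuronal list stayed above, with a matched mean of 71.3% and an adjusted permutation p of 0.00135 (range over its 10 alternatives 0.00135 to 0.0364). For promoter peaks, ranges over alternatives here and below mix adjusted p-values of exact tests with that of this permutation test. Matched lists here and below could hold olfactory and vomeronasal receptor genes, which were seldom marked and can lower matched means. Matching without these genes was not run. The other 10 lists were not past the matched permutation test. In 9 of them, all but the GABAergic list, every member was marked, so none of the 9 could have reached a lower p there. Matched means were 94.2 to 97.3% for the housekeeping, chromatin acetylation, cell cycle, immediate early, upper-layer and axon guidance lists. They were 95.5% for GABAergic genes (adjusted permutation p 1.0, range over 10 alternatives 0.00369 to 1.0), 87.9% for radial glia (0.124, range 0.00262 to 0.124), 81.1% for synaptic genes (0.0810, range 0.00262 to 0.0810) and 76.1% for deep-layer genes (0.117, range 0.0164 to 0.117). Of the 11 lists, 4 lost the call with starts restricted to the gene's own 5′ end and 5 with predicted, olfactory and vomeronasal genes left out of the background.

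Hox genes and genes of other organs and of the germline were seldom marked. Of the 39 Hox genes, which pattern the trunk and hindbrain, 2 carried a replicated peak (5.13%), at Hoxa7 (fold 5.98) and Hoxd1 (2.78), and the Hoxd1 peak overlapped a peak of neither replicate. Hoxa1, Hoxa10 and Hoxa11 were among the 37 without. None of 11 microglia genes had a replicated peak, including Aif1, C1qa and C1qb, while replicate 2 alone had peaks at Cx3cr1 and Tmem119, chosen after their values were seen. Among 14 liver genes only the transferrin gene Trf (4.72) was marked, and Afp, Ahsg and Alb, which encode plasma proteins, were not. Of 15 heart and muscle genes 3 were marked, the sarcomere genes Myh7 (8.09), Myl2 (3.42) and Tnni3 (3.25), and Acta1, Actc1 and Ckm were among those without. Of 12 germline and pluripotency genes 2 were marked, the meiotic methyltransferase gene Prdm9 (23.0) and the RNA-binding protein gene Dazl (12.8), and Ddx4, Dppa3 and Mael were among those without.

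These 5 lists lay below other genes by the same two-sided Fisher's exact test, with adjusted p 3.46e-13 for Hox, 0.000148 for microglia and for liver, 0.00449 for heart and muscle and 0.00504 for germline. Hox genes lie side by side in clusters on chromosomes 2, 6, 11 and 15. Exact and permutation tests take genes as independent, so the p-values of the Hox list are too small. Hox and germline genes stayed below lists matched on promoter CpG and GC content, with matched means of 89.9% and 73.8% and an adjusted permutation p of 0.00135 for each (ranges over 10 alternatives, exact tests included, 9.56e-18 to 0.00135 and 0.000422 to 0.0106). Microglia genes could not have been past that test, since 0 of 11 marked is the lowest outcome (matched mean 16.6%, adjusted permutation p 0.519, range 5.05e-06 to 0.519). The calls ended there for liver (matched mean 27.0%, adjusted permutation p 0.176, range 5.05e-06 to 0.176) and for heart and muscle (44.9%, 0.0952, range 0.000193 to 0.0952). With only peaks of −log10 q of at least 5, 8 lists lay below other genes.

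The other 11 lists were not past the threshold. Among progenitor and neuronal lists, 9 of 10 intermediate progenitor genes were marked (exact adjusted p 0.144), with Insm1 (31.9), Btg2 (19.8), Sstr2 (19.7) and Gadd45g (14.7) highest and Neurod4 without a replicated peak. All 8 Cajal-Retzius genes were marked (exact adjusted p 0.0862), with the secreted glycoprotein gene Reln (20.9), Cxcr4 (14.7), Nhlh2 (13.1) and Calb2 (7.96) highest. Of 13 imprinted genes 12 were marked (exact adjusted p 0.0641), including Igf2r (22.9), Peg10 (22.6), Nnat (16.7) and Mest (14.1), and Ndn was not.

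Glial lists were split. Of 10 astrocyte genes 7 were marked (exact adjusted p 1.0), with the transcription factor gene Nfia (29.4), Fgfr3 (23.2), the glutamate transporter gene Slc1a2 (20.3) and Gja1 (7.21) highest, and the mature markers Aqp4, Gfap and S100b were not. Of 12 oligodendrocyte lineage genes 7 were marked (exact adjusted p 0.828), with Cnp (14.5), Mbp (13.2), Myrf (9.18) and Pdgfra (5.56) highest, and Mag, Mog, Nkx2-2, Plp1 and Sox10 were not. The Mbp peak (chromosome 18, 82474770 to 82476403) lay at the outer start of the gene, which spans 82475146 to 82585637. Whether starts further inside Mbp were marked was not examined. Sox10 had a peak in replicate 1 alone (4.12).

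Lists of other cell types of the dissected tissue were marked in part. Endothelial and pericyte genes were marked at 6 of 12 (exact adjusted p 0.436), with Kdr (8.17), Pdgfrb (6.58), Erg (5.84) and Flt1 (4.51) highest and Cdh5, Pecam1 and Rgs5 among those without. Erythroid genes were marked at 4 of 11 (exact adjusted p 0.0943), namely Klf1 (10.6), Gypa (9.19), Epor (6.02) and Tal1 (4.16), with Alas2, Gata1 and Hba-a1 among those without, Hba-a1 being uncertain because of its near-identical copy. Choroid plexus genes were marked at 5 of 10 (exact adjusted p 0.576), namely Foxj1 (9.43), Kl (7.37), Lmx1a (5.97), Msx1 (4.63) and Otx2 (3.96), and not at Aqp1, Cldn2, Folr1, Kcne2 and Ttr. Meningeal and fibroblast genes were marked at 4 of 10 (exact adjusted p 0.237), namely Twist1 (9.20), Foxc1 (5.56), Col1a2 (4.14) and Igf2 (3.62), with Col1a1, Col3a1 and Dcn among those without.

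Regulators of the diencephalon, itself a part of the forebrain, and of the neighbouring midbrain and hindbrain were marked in part. Of 12 diencephalon genes 8 were marked (exact adjusted p 1.0), with Lhx9 (9.27), Tcf7l2 (9.09), Six3 (8.17) and Irx3 (6.03) highest, and Foxb1, Gbx2, Nkx2-4 and Otp were not. Of 16 midbrain and hindbrain genes 8 were marked (exact adjusted p 0.367), with Mafb (16.8), Egr2 (9.41), Fgf8 (6.17) and En2 (5.16) highest and En1, Gata3 and Lbx1 among those without. Replicate 1's own list marked 11 of these 16 genes and replicate 2's marked 8, and En1 had a peak in replicate 1 alone (4.04). Both lists lay below CpG-matched random lists, whose means were 96.2% for diencephalon (adjusted permutation p 0.00432, range over 10 alternatives 0.00432 to 1.0) and 93.6% for midbrain and hindbrain (adjusted permutation p 0.00135, range 0.00135 to 1.0).

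**Figure D2:**
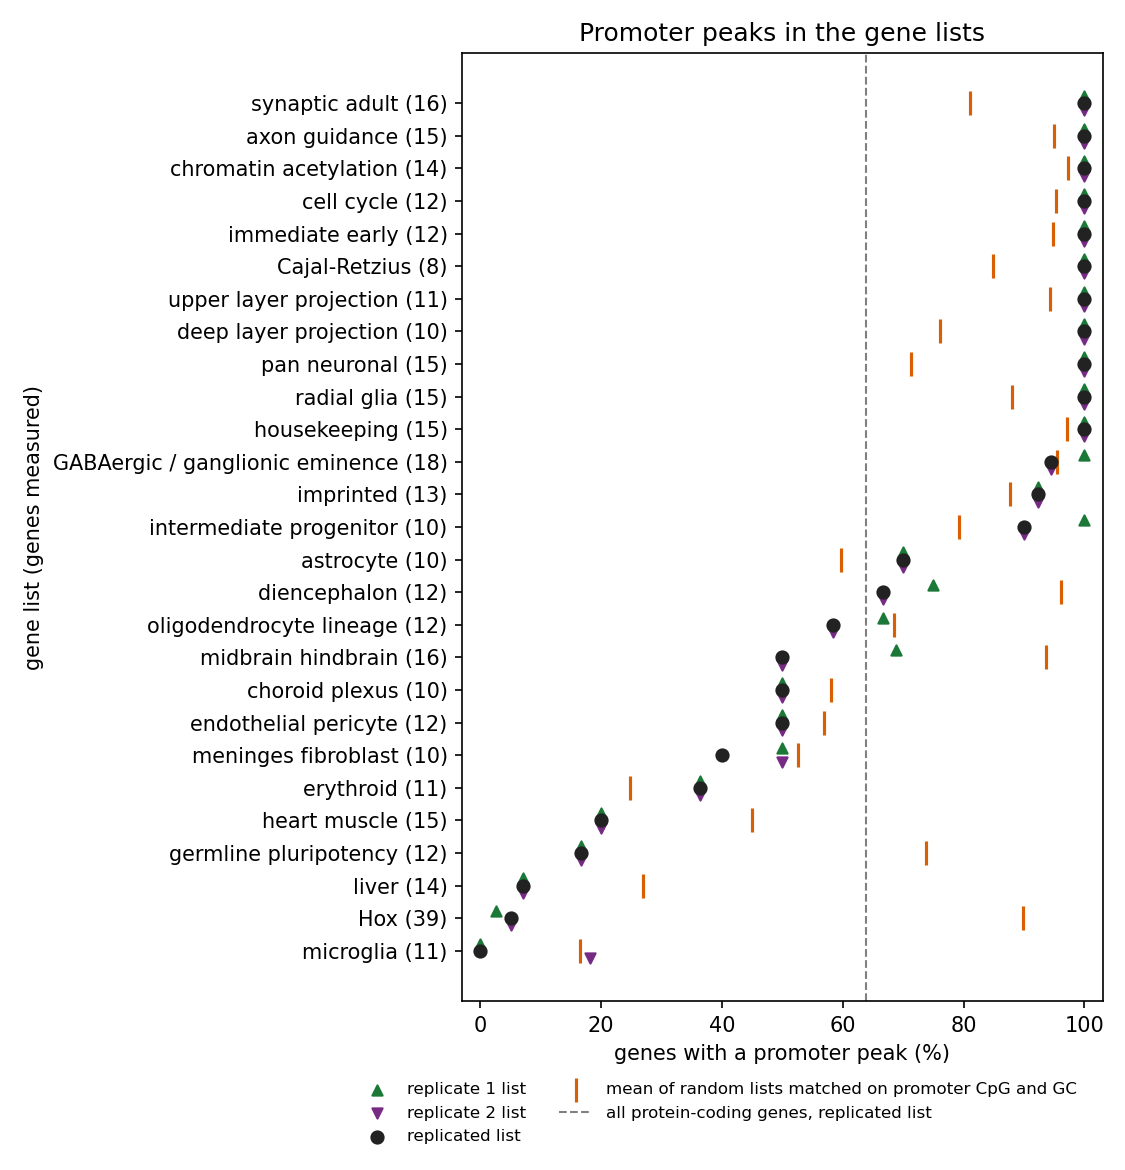
The horizontal axis gives the percentage of each gene list with a promoter peak, as circles for the replicated list and triangles for each replicate's own list, and the vertical axis names the lists with the genes measured. Orange ticks give the mean of random lists matched on promoter CpG and GC content, and the dashed line marks 63.9% of all protein-coding genes.

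Away from gene starts, distal peaks were most frequent near upper-layer, radial glia, deep-layer and GABAergic genes. Upper-layer genes lay nearest to a mean of 11 distal peaks per gene, led by Pou3f3 with 38, the transcription factor gene Mef2c with 25 and Pou3f2 with 17. Radial glia genes had a mean of 6.87, led by Sox2 with 32, Sox9 with 14 and the receptor gene Notch1 with 12. GABAergic genes had a mean of 5.39, led by Meis2 with 21 and Dlx6 with 14. Deep-layer genes had a mean of 5.9, with 24 distal peaks nearest to Bcl11b, and the 39 Hox genes had a mean of 0.0769. Genes named here for their distal counts were chosen after their values were seen. Peaks were counted singly, so a wide region split into several peaks counts several times. Merged over gaps of at most 1000 bp, the domains over Pou3f2, Sox2, Pou3f3 and Meis2 held 17, 10, 8 and 7 peaks, promoter peaks included. Counts of merged distal regions were not tested.

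In all, 13924 replicated peaks (39.9%) lay over 2500 bp from any protein-coding start, at a median of 27.0 kb, a mean of 0.643 per gene. Against 10000 random lists of the same size, the adjusted two-sided permutation p was 0.0018 for the upper-layer, radial glia and GABAergic lists, where the unadjusted p of 0.0002 was the smallest possible. It was 0.0108 for deep-layer genes, 0.0177 for axon guidance (mean 3.6) and pan-neuronal genes (mean 3.47), 0.0196 for immediate early genes (mean 3.67) and 0.0396 for intermediate progenitor genes (mean 3.5), by the same permutation test. Hox genes lay below random lists, with an adjusted permutation p of 0.00405. The remaining 18 lists were not past the threshold.

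Random lists matched on the length of the genomic stretch nearest to each gene kept 4 of these calls. Adjusted permutation p was 0.0054 for upper-layer genes (matched mean 1.64, range over 7 alternatives 0.00135 to 0.0054), 0.0081 for radial glia (1.26, range 0.00135 to 0.0081), 0.0297 for GABAergic genes (1.35, range 0.00135 to 0.0297) and 0.0297 for immediate early genes (0.632, range 0.0216 to 0.0420). The calls ended there for deep-layer (matched mean 1.72, permutation p 0.0936, range 0.00848 to 0.0936), axon guidance (1.72, p 0.236, range 0.00848 to 0.236), intermediate progenitor (0.766, p 0.0788, range 0.0324 to 0.109), pan-neuronal (1.52, p 0.220, range 0.00848 to 0.220) and Hox genes (0.173, p 0.654, range 0.00135 to 0.654). Matched lists held 20.4% of the deep-layer excess over random lists, 4.53% of the intermediate progenitor, 31.2% of the pan-neuronal and 36.6% of the axon guidance excess, and 82.98% of the Hox deficit. The Hox call also ended with only peaks of −log10 q of at least 5, and the intermediate progenitor call held in 3 of its 7 alternatives.

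**Figure D3:**
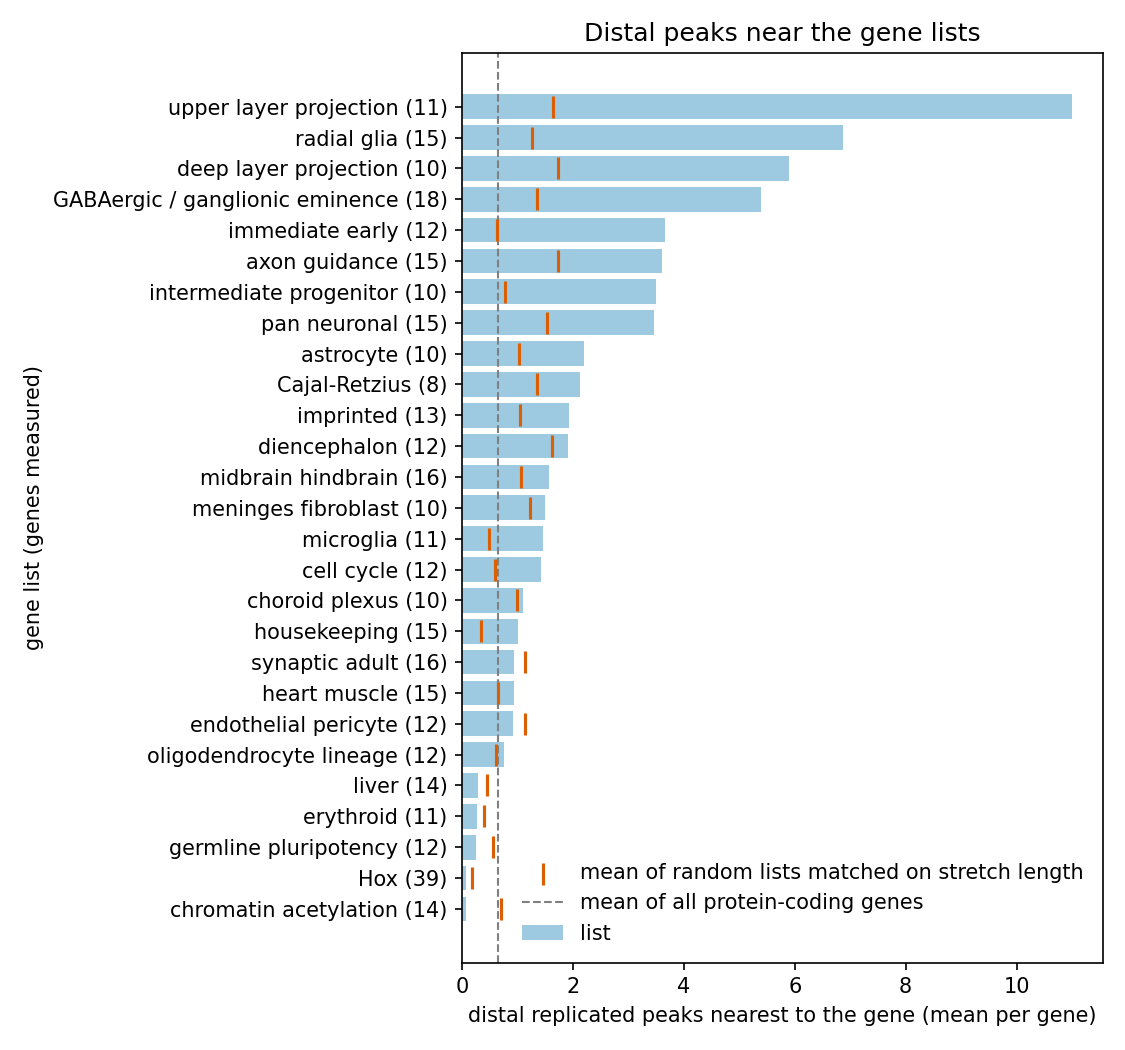
Bars give the mean number of distal replicated peaks per gene in each list, with the genes measured beside its name, and orange ticks give the mean of random lists matched on stretch length. The dashed line marks 0.643 peaks per protein-coding gene, and the upper-layer list is highest at 11.

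Several of the strongest distal peaks lay over long non-coding RNA genes. The strongest, with a fold of 47.2, covered part of Mir9-3hg, host gene of a neural microRNA, at chromosome 7, 79498898 to 79510511. It was followed by peaks at Lncppara (43.4, nearest protein-coding gene Ppara), C130071C03Rik (42.8, nearest Mef2c) and Gm48623 (38.8, nearest Cplx2). Then came a peak nearest to Mef2c (37.9) with its summit outside annotated genes. The next were at 1110038B12Rik (37.7, nearest Hspa1b), AI849053 (37.0, nearest Rhbg), a site nearest to Zfp869 (36.4), 1810026B05Rik (35.9, nearest Chd2) and a site nearest to Pum2 (33.7). The summits of the peaks nearest to Zfp869 and Pum2 also lay outside annotated genes.

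The widest acetylated domains lay over microRNA miR-9 loci and transcription factor genes. Merging replicated peaks over gaps of at most 1000 bp gave 24781 domains with a median width of 1.02 kb, of which 49 were at least 10 kb wide. The widest, 35.7 kb at chromosome 3, 88197093 to 88232760, overlapped Mir9-1 and had no protein-coding start. The next, 30.1 kb at chromosome 13, 83712835 to 83742906, overlapped Mir9-2 and C130071C03Rik. A domain of 26.4 kb at chromosome 7, 79495918 to 79522280, overlapped Mir9-3. The Foxg1 domain, 29.0 kb at chromosome 12, 49373266 to 49402248, held 16 peaks and also a start of Gm43517. Other wide domains lay over Nfix (27.98 kb), Bcl11a (26.9 kb, with A830031A19Rik), Nfib (25.1 kb), Meis2 (24.3 kb), Pou3f3 (23.2 kb), Mn1 (21.1 kb), Pou3f2 (18.8 kb), Sox2 (18.3 kb), Zeb2 (17.7 kb) and Nr2f1 (17.5 kb), all genes of transcriptional regulators. Lncppara lay in a domain of 17.2 kb.

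**Figure D4:**
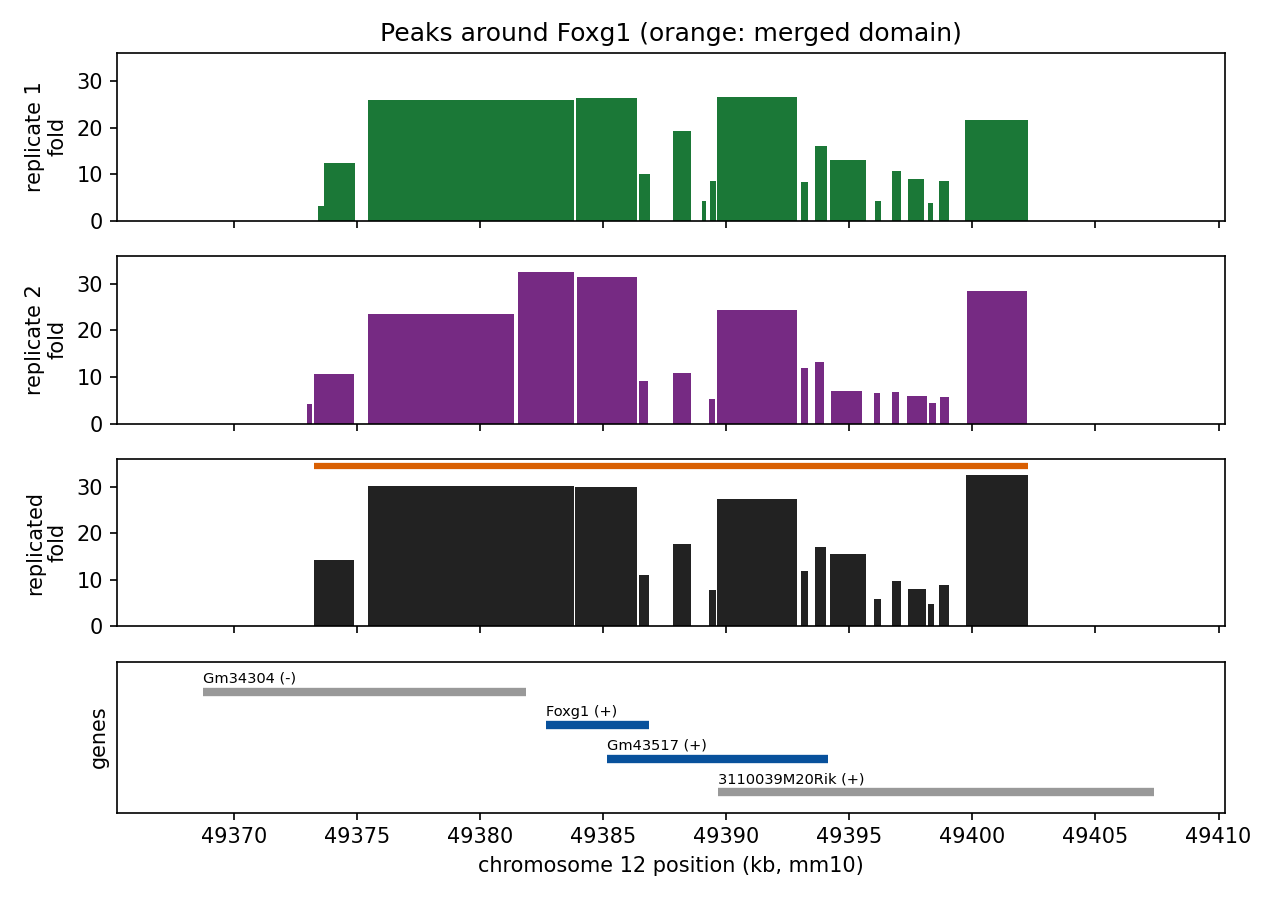
The top 3 panels show peaks around Foxg1 on chromosome 12 (horizontal axis in kb, mm10) as bars of their own width, with fold over background as height, in replicate 1, replicate 2 and the replicated list. The orange line marks the merged domain of 29.0 kb with 16 replicated peaks, and the lowest panel shows protein-coding genes in blue and non-coding genes in grey.

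Peak summits lay mostly on the transcribed side of gene starts. Of summits within 1000 bp of the nearest start, 13500 of 19971 in replicate 1 lay downstream (67.6%, interval 66.9 to 68.2%), as did 13266 of 19378 in replicate 2 (68.5%, 67.8 to 69.1%). The median position was 131 bp downstream in both replicates.

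**Figure D5:**
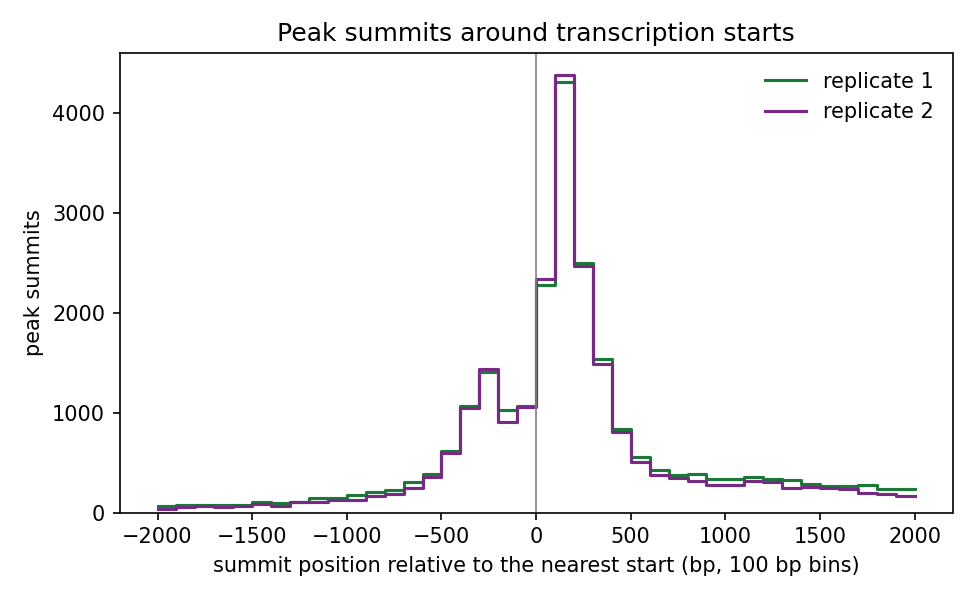
The horizontal axis gives the summit's position relative to the nearest protein-coding start in bins of 100 bp, and the vertical axis the number of peak summits, as a line per replicate. Of summits within 1000 bp of the start, downstream positions hold 67.6% in replicate 1 and 68.5% in replicate 2.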

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

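Peaks outside the chromosomes used for the gene comparisons stood out because signal was present where no gene comparison of the report looked. Peaks there did enter the overlap of the replicates, and those on Y the share at promoters. The replicated list held 4 peaks on the Y chromosome. They lay at the starts of Kdm5d (897841 to 898239, fold 4.55), Uty (1244952 to 1245678, fold 6.37) and Ddx3y (1285852 to 1286089, fold 5.16), and at 90744389 to 90744597 (fold 4.04), where the nearest protein-coding start, of Gm21860, was 10224 bp away. A further 9 replicated peaks lay on unplaced sequences, 5 of them on 1 sequence assigned to X, and the strongest, with a fold of 21.95, lay on a sequence assigned to chromosome 4. The libraries were pools of male and female embryos, per the labels.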

How the results depend on the processing

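No paired analysis was possible because the labels give only 1 group. The replicated peaks overlapping both replicates were chosen as an alternative after the data were seen. Under the alternatives, 71 of the values that answer a comparison stayed the same and 32 moved, and for single lists 403 stayed the same, 30 lost their call, 9 gained one and 17 changed sign. With 50% overlap, rho was 0.915 and replicate 2 had 17079 peaks without a partner. With equally many top peaks, rho was 0.903 and replicate 1 had 12117 such peaks and replicate 2 had 10461. With only peaks of −log10 q of at least 5, these peaks numbered 4379 in replicate 1 and 1226 in replicate 2, because fewer peaks entered, and rho was 0.880 and kappa 0.949. The ratio of median folds at promoters to elsewhere, 3.21, was then 2.57 and the width ratio, 2.63, was 1.89, 8 lists lay below other genes, 0 lists had fewer distal peaks than random lists, and downstream summits were 71.6% and 72.8%. Differences from other genes were then −3.31 points for diencephalon and −11.6 for astrocyte, from 2.79 and 6.12, and −0.0379 distal peaks per gene for heart and muscle, from 0.293. The fold and width ratios were 3.02 and 2.23 with peaks overlapping both replicates, 3.42 and 3.24 with the pooled list, 2.78 and 2.36 with the 2500 bp window, and the fold ratio was 3.44 with the 500 bp window. Leaving out each replicate gave fold ratios of 2.86 to 2.95 and width ratios of 3.07 to 3.34, oligodendrocyte differences of −5.48 to 1.91 points, midbrain and hindbrain differences of −13.8 to 4.00 points and heart and muscle distal differences of −0.279 to 0.249, the sign turning with replicate 1's list alone. The pooled list gave 2.07 points for oligodendrocyte genes, from −5.55. Astrocyte differences were −3.32 with the 500 bp window and −0.757 with only the gene's own 5′ end, where 7 lists lay above other genes. Without olfactory, vomeronasal and predicted genes 6 lists lay above, and diencephalon and astrocyte differences were −6.29 and −2.96. Against CpG-matched lists 1 lay above, a test that 10 lists, Cajal-Retzius included, did not pass although every member was marked, and differences were −1.07 for GABAergic genes, −29.5 for diencephalon and 11.6 for erythroid genes, from 30.6, 2.79 and −27.5. Distal differences for endothelial genes, 0.281, were −0.0374 with peaks overlapping both replicates and −0.218 against lists matched on stretch length, where synaptic genes were at −0.191, from 0.289, 4 lists lay above and 0 below. Downstream summits within 500 bp were 68.8% and 69.4%. Except where fewer peaks entered, the cause was not tested. Unknown depth limits what can be said of weak peaks.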

Other observations

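The families, domain widths and tests of this part were chosen after the results were seen, except the test that removed peaks at long non-coding RNA starts and the random lists matched on CpG content or stretch length, which were planned, although the bounds set on these lists were not. No biological explanation was tested because the design has 1 group. Families of genes used in every cell were marked at nearly all members, with 46 of 46 mitochondrial complex I genes, 76 of 79 ribosomal protein genes (96.2%) and 42 of 45 proteasome genes. Zinc finger protein genes were marked at 340 of 394 (86.3%, median fold 19.4). Sensory receptor families were almost unmarked, with 2 of 1134 olfactory receptor genes (0.176%) and 1 of 329 vomeronasal receptor genes. The clustered protocadherins, neuronal adhesion genes with many alternative first exons, had peaks at 2 of 14 alpha, 0 of 22 beta and 9 of 21 gamma genes (42.9%). Their copies are similar, and the placement of peaks among them, as among the 54 of 64 marked histone genes, is uncertain.

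Some genes with a CpG-rich promoter but without the mark belonged to families of developmental transcription factors. Of the 284 such genes, 60 (21.1%) fell in 11 transcription factor and Wnt families and the rest outside them. The rest was not sorted by function and also holds developmental regulators, such as En1, Gbx2 and Hand2. The 11 families held 137 of the 10939 genes with a CpG-rich promoter, and outside them 2.07% of such genes were unmarked. The families were picked after the results were seen, so only counts are given. Unmarked were 26 of 28 CpG-rich Hox genes, 11 of 35 Fox genes, 7 of 10 Nkx genes, 4 of 7 Tbx genes and 2 of 5 Gata genes. The 5 unmarked of 7 Pax genes were Pax1, Pax3, Pax5, Pax7 and Pax9. Of the other families, 0 of 8 Lhx and Lmx, 2 of 15 Sox, 1 of 14 Wnt, 1 of 6 Irx and 1 of 2 Pitx genes were unmarked. Domain widths differed between lists too. The median domain at a promoter was 1.67 kb for other genes and 6.14 kb for radial glia, 6.11 kb for GABAergic, 4.85 kb for deep-layer, 4.33 kb for pan-neuronal, 4.15 kb for upper-layer and 3.775 kb for axon guidance genes (adjusted permutation p 0.000733 for each, two-sided, 10000 random lists). It was 3.63 kb for immediate early, 3.30 kb for intermediate progenitor, 2.62 kb for housekeeping, 2.59 kb for imprinted and 2.53 kb for synaptic genes (adjusted permutation p 0.00126 to 0.0244). With random lists matched on promoter CpG and mean log2 widths, imprinted genes were not past the threshold (adjusted permutation p 0.202). In that test 5 astrocyte genes lay above matched lists (adjusted permutation p 0.0238) and 6 Cajal-Retzius genes below (0.0403). Neither list was past the unmatched permutation test (adjusted p 0.232 and 0.0939). Only genes with a start inside a domain entered, which leaves out marked genes whose peak lies beside the start, and lists with few such genes, such as midbrain and hindbrain with 3, are not described.

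Of the 34941 replicated peaks, 5880 (16.8%) did not overlap a peak of both replicates, and 414 overlapped a peak of neither. The 5880 had a median fold of 3.47 and a median width of 248 bp, and 18.96% lay at promoters, beside 8.34, 761 bp and 59.7% for the 29061 that overlapped both. Among distal peaks, 1172 (8.42%) lay within 1000 bp of a long non-coding RNA start and had a median fold of 5.68, beside 4.12 for the other 12752. Of the 10 strongest distal peaks 7 lay at such a start, and of the strongest 100, 43 did.

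Gene lists differed in how often they carried a promoter peak, and promoter CpG content is a candidate explanation. Random lists matched on CpG and GC content held a median of 85.8% of the excess of the 11 lists above other genes, but 33.8% for deep-layer and 47.8% for synaptic genes, and a median of 65.1% of the deficit of the microglia, liver and heart lists, but 43.2% for heart. This goes with CpG content holding most of the excess in the lists near or over the median of 85.8%. It leaves open the deep-layer and synaptic lists, which were marked at every member and could not have come closer to passing the matched test. The microglia, liver and heart lists stay open too. Matched lists could hold the almost unmarked olfactory and vomeronasal receptor genes, which can lower matched means and raise the share held of a deficit. Matching without these genes was not run. CpG content as matched here is argued against for the pan-neuronal list, where matched lists held 20.6% of the excess and the list stayed above them (adjusted permutation p 0.00135, range over its alternatives 0.00135 to 0.0364). Receptor genes in the matched lists can also lower this 20.6%, so its size is uncertain. For the Hox and germline lists matched lists lay above other genes, so that they held a median of −32.5% of the deficit (−44.04% for Hox and −21.01% for germline).

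Upper-layer, radial glia, GABAergic and immediate early genes lay nearest to more distal peaks than random lists, which could come from long stretches of sequence around such genes. Lists matched on stretch length held a median of 12.5% of the excess of the 8 lists above random lists, which argues against stretch length as the larger part, although 4 of the 8 lost their call in that test. Without Sox2, Pou3f3, Meis2 and Ier2 the means were 5.07 for radial glia, 8.3 for upper-layer, 4.47 for GABAergic and 3.09 for immediate early genes. Lists matched on stretch length had means of 1.19, 1.61, 1.30 and 0.633, so a single gene did not hold the whole excess. The largest permutation p of the 4 lists was 0.0156, not adjusted over all lists as the calls were. Whether each call rests on a single gene therefore stays open. Starts of long non-coding RNA genes counted as distal peaks are argued against, since without peaks near them the largest permutation p of the 4 lists was 0.0048. How far wide regions split into several peaks raised the counts was not tested. Whether these peaks act on the nearest gene stays open.

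X-linked genes carried a promoter peak less often than autosomal genes, and a low CpG content of X promoters is a candidate explanation. Genes with a CpG-rich promoter made up 28.4% of X genes and 51.5% of autosomal genes, and autosomal genes matched on CpG and GC content held 82.4% of the deficit. The matched genes included the almost unmarked olfactory and vomeronasal receptor genes, which can raise this share. Matching without them was not run, so how much of the deficit goes with CpG content stays open. CpG content is argued against as the whole of the deficit, since X genes lay −2.88 points from matched genes (two-sided permutation p 0.0064). Whether weaker signal on X was lost at the detection limit stays open. Among genes with a CpG-rich promoter the share with a peak differed by −2.29 points, but nearly all were marked, so little loss could show. Among other genes it was 29.6% on X and 29.7% on autosomes. There the almost unmarked olfactory and vomeronasal receptor genes were not set apart. The median fold of marked X-linked genes with a CpG-rich promoter was 0.631 of that on autosomes, which goes with weaker signal.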
